A study of Mus musculus with 10 samples.

How the data were processed

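Gene expression was measured by RNA-seq in 10 libraries of sorted mouse macrophages, and 1 table of all libraries was used. Per the labels' protocols, RNA was extracted with either of 2 kits, amplified with a SMART-Seq v4 low-input kit and made into Nextera XT libraries, which carry no strand information, so reads of a gene and its antisense partner cannot be told apart. The table holds FPKM, deposited by the authors as fragments per kilobase of gene scaled by library size, with 1 column per library. STAR and edgeR, and the builds mm10 and GRCm38, are named per the submitters' processing notes, with no version or role. The gene lengths, the library scaling and the filter on genes are not given in the sources used here. Each column was matched to its sample by title, and all 10 columns were used.

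The table held 12535 genes, 316 of them without a symbol, and 312 of those symbols were found by identifier in a reference table. Coordinates come from the GENCODE M21 annotation of GRCm38, 1-based. Whole reads were recovered from the low FPKM values: with the longest annotated transcript as gene length, 85.8% to 87.1% of the values between 1 and 200 reads in a library came out whole within 0.05. The rule for the size of 1 read was changed after its first form had failed in cKO-labelled TAM replicate 3. The recovered depth per library was 10312725 to 26454659 reads, which is exact only for genes whose length matches. No count test was run as the main test, since FPKM are not counts.

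Before averaging, the libraries of a group were compared with each other. Over the 12 same-group pairs, the median squared difference was 1.76 to 2.92 times that of counting noise, which 1 library entered under 2 names would not give. Each library was treated as 1 replicate, though libraries made from 1 pool of cells would also pass this check.

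Genes with an FPKM of at least 1 in at least 3 of the 10 libraries were tested (11127 genes). Limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) for all 10 libraries in 1 model with 3 group means (7 residual degrees of freedom), with empirical Bayes moderation and a trend on mean expression, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Values are given as mean FPKM ± SD over the libraries of a group, with n = 4 for resident macrophages and n = 3 for either TAM group. The comparisons were control TAM against resident macrophages and cKO-labelled TAM against control TAM.

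Before the data were examined, 34 gene lists were fixed, for pathways, sample quality and the cell types that the sort could hold, and the tests, alternatives and rule for naming genes were fixed with them. Lists with at least 5 tested members (32 lists) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data and with fry. A count adjusted over the list alone uses the p-values of its members only. Genes are named by this rule: Ahr and 5 classical targets where tested (Cyp1a1 and Nqo1 are not analysed here); per comparison the 5 largest rises and 5 largest falls among genes past the threshold with a mean FPKM of at least 10 in the higher group, no overlap of the groups and a proper gene symbol; for each list called, or with at least 3 members past the threshold, up to 4 such members with the largest change; the 2 members with the smallest p of the AhR target, activation, interferon, MHC class II and chemokine lists; and the 2 most abundant members of each cell type or quality list. The text names part of the genes that the rule returns, and that part was picked after their values were seen. Lyz1, the Y-linked genes, Xist, and in the second comparison Arg1, Chil3, Lpcat2 and Timd4, were chosen after their values were seen. The peritoneal macrophage lists were written after the main results were seen.

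The fit was tested on simulated data, with 10 draws per comparison of 200 changed genes among the 11127. For control TAM against resident macrophages, 85.2% of the genes changed by 1.5-fold and 98% of those changed by 2-fold were recovered, and 5.00% of the calls were false. For cKO-labelled against control TAM these were 80.4%, 95.6% and 4.53%. The simulated noise was that of the libraries, so the figures say nothing about mice beyond them. Only 200 genes were changed per draw, while 8577 and 4410 genes were called in the data. The Benjamini-Hochberg cut-off depends on that share, so the rates of recovery and of false calls need not hold for the data.

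The alternatives were pseudocounts of 0.1 and 0.5, no filter, an FPKM of at least 5 in 3 libraries, rescaling each library to a common total, quantile normalization, median-of-ratios scaling, only the 2 groups compared, no variance trend, array weights, the replicate number as a block, leaving out each library in turn, and a 2-fold limit. Chosen after seeing the data were limma voom on the recovered reads (10 genes without a usable length left out) and removal of the acinar list with rescaling. Figures were drawn with matplotlib 3.10.9.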

Results

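RNA from mouse macrophages was sequenced in 10 libraries of 3 groups. Cells positive for CD45, CD11b and F4/80 (the pan-leukocyte, myeloid and macrophage surface markers) were sorted from the healthy pancreas of wild-type C57BL/6 mice (resident macrophages, n = 4) and from orthotopic pancreatic tumours 14 days after KPC organoid cells, a mouse model of pancreatic ductal adenocarcinoma, had been implanted. Tumour-associated macrophages (TAM) came from Ahr fl/fl mice (control TAM, n = 3) and from Ahr fl/fl mice labelled as carrying LysM, in which Cre recombinase from the Lyz2 locus is meant to delete the aryl hydrocarbon receptor gene in myeloid cells (cKO-labelled TAM, n = 3). The deposited FPKM table held 12535 genes. Recovered depth ran from 10312725 reads in control TAM replicate 2 to 26454659 in cKO-labelled TAM replicate 3. Libraries of 1 group were close to each other: among genes of 100 to 1000 FPKM the median coefficient of variation was 3.27% in resident, 2.41% in control TAM and 2.49% in cKO-labelled TAM libraries. The series text gives mouse numbers, but the p-values below measure only the spread between these libraries.

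Ahr, the targeted gene (ENSMUSG00000019256, GRCm38 chromosome 12, 35497974 to 35535038, minus strand, protein-coding), was measured first in every library. Its FPKM was 3.84, 4.46, 4.29 and 4.16 in the resident libraries, 7.11, 6.91 and 7.51 in control TAM, and 10.2, 11.2 and 9.65 in the libraries labelled cKO. The mean was thus higher in cKO-labelled TAM (10.4 ± 0.785 FPKM, SD, n = 3) than in control TAM (7.18 ± 0.309, n = 3), with a log2 change of 0.47 ± 0.07 (SE) and a limma adjusted p of 0.000108. A gene-level FPKM also counts exons outside the part that Cre removes, so this value does not check the deletion, and the group is called by its label throughout. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321, minus strand), the lysozyme gene whose locus carries the Cre, fell from 19904 ± 85.1 FPKM in control TAM to 11460 ± 203 in cKO-labelled TAM (log2 change -0.80, adjusted p = 9.39e-13).

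Of 6 tested genes known to be induced by the receptor, 4 were lower in the cKO-labelled libraries. Cyp1b1 (ENSMUSG00000024087, chromosome 17, 79701537 to 79715061, minus strand), a cytochrome P450, was at 2.05 ± 0.155 FPKM in control TAM and 0.783 ± 0.0535 in cKO-labelled TAM (log2 change -0.77 ± 0.08, adjusted p = 1.82e-06). Tiparp, a mono-ADP-ribosyltransferase that feeds back on the receptor, fell from 34.4 ± 0.366 to 27.1 ± 0.501 FPKM. Serpinb2 fell from 454 ± 10.5 to 377 ± 5.68 FPKM and Entpd1 from 52.9 ± 2.87 to 46.7 ± 1.06 FPKM. Ahrr, the receptor's repressor, was at 0.467 ± 0.0852 and 0.353 ± 0.163 FPKM, which did not differ past the threshold (adjusted p = 0.337). Nor did Lpcat2, at 119 ± 1.84 and 118 ± 4.29 FPKM (adjusted p = 0.930). Of the 6 tested members of the AhR target list, 4 fell and 0 rose (4 adjusted over the list alone). The list was called lower (adjusted p = 0.0117), a call lost with an estimated correlation (adjusted p = 0.245) and with the filter on low values removed. The raised filter left too few members to test. Of all 11127 genes tested, 2127 were lower in cKO-labelled TAM. Serpinb2 is also strongly expressed by peritoneal macrophages. Of 15 markers of large peritoneal macrophages, 7 fell and 2 rose in the same libraries, with a median log2 change of only -0.09. The macrophage identity list was also lower there, and the acinar and B cell lists higher, as given below. A changed cell mix thus cannot be told apart from lower receptor activity here. Between resident macrophages and control TAM, Ahr rose from 4.19 ± 0.261 to 7.18 ± 0.309 FPKM. Of the 6 targets 4 rose and 2 fell there (6 adjusted over the list alone). Cyp1b1 rose from 0.274 ± 0.0373 to 2.05 ± 0.155 FPKM, Serpinb2 from 9.29 ± 0.881 to 454 ± 10.5 and Lpcat2 from 41.8 ± 3.19 to 119 ± 1.84. Ahrr fell there from 1.10 ± 0.111 to 0.467 ± 0.0852 FPKM, and the list was not called (adjusted p = 0.109). The receptor complex list held 6 tested members and was not called in either comparison, with 2 members risen and 2 fallen in control TAM against resident macrophages (adjusted p = 0.897, 4 adjusted over the list alone) and 2 risen and 1 fallen in cKO-labelled against control TAM (adjusted p = 0.448, 5 adjusted over the list alone).

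**Figure D1:**
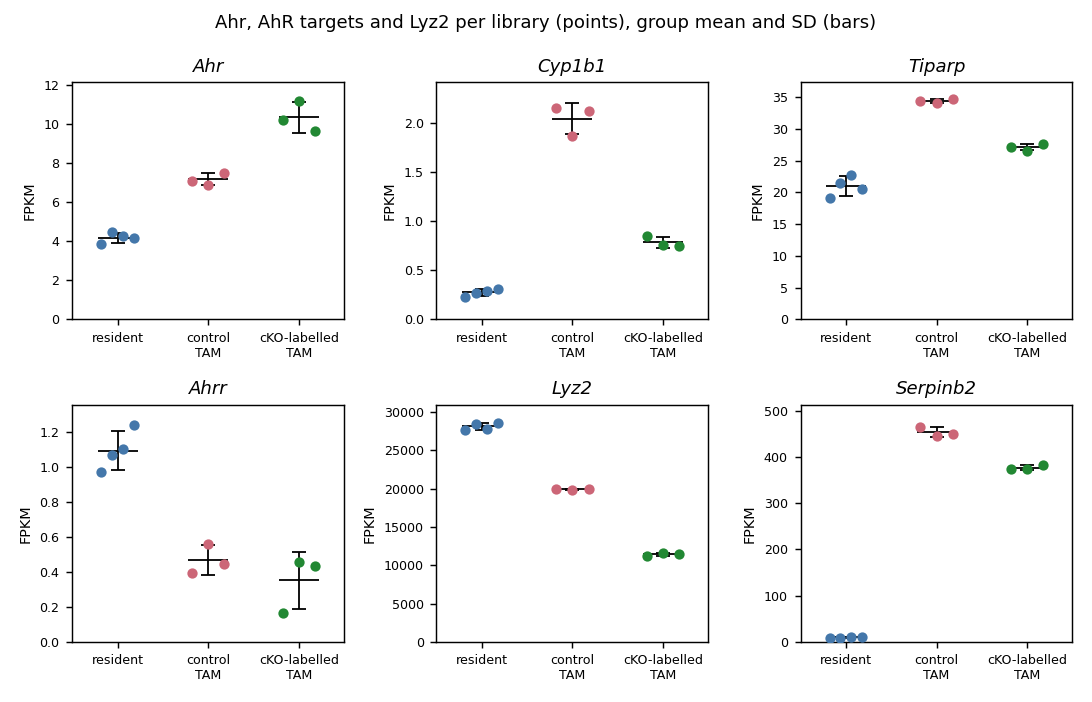
FPKM (y axes from 0) of Ahr, 4 genes of the AhR target list and Lyz2 in each of the 10 libraries (points), with group means and SD (bars). The 3 cKO-labelled libraries lie between 9.65 and 11.2 FPKM for Ahr, above the control TAM libraries, and below them for Cyp1b1, Tiparp, Lyz2 and Serpinb2.

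The first comparison asked how macrophages of the tumour differ from those of the healthy pancreas. Macrophages of control tumours held far more mRNA of Arg1, the arginine-degrading enzyme arginase 1 (8.48 ± 0.407 FPKM in resident, 3269 ± 55.3 in control TAM), of Spp1, which encodes osteopontin (5.21 ± 0.198 and 1056 ± 9.31), and of the chitinase-like protein gene Chil3 (2.35 ± 0.298 and 399 ± 3.71). The largest rise among named genes was that of Retnlg, a member of the neutrophil list (0.332 ± 0.245 and 1166 ± 14.9 FPKM), and AA467197 rose from 0.330 ± 0.225 to 158 ± 4.77 FPKM. Among the markers of tissue-resident macrophages, all 21 tested members fell (21 adjusted over the list alone, median log2 change -2.76, adjusted p = 1.10e-14). The C-type lectin Cd209f fell from 773 ± 14.1 to 1.54 ± 0.140 FPKM, the haptoglobin scavenger receptor Cd163 from 345 ± 5.33 to 11.6 ± 1.40, and Gas6, a ligand of receptor tyrosine kinases, from 550 ± 8.66 to 21.8 ± 0.314. Of the monocyte programme, 14 of 15 tested members rose and 0 fell (14 adjusted over the list alone, median log2 change 3.11, adjusted p = 6.17e-08), with Plac8 rising from 9.84 ± 0.472 to 364 ± 7.98 FPKM and Ly6c2, the antigen of inflammatory monocytes, from 0.944 ± 0.150 to 24.1 ± 1.11. In the same libraries the neutrophil list was also higher, and the acinar and B cell lists lower, as given below.

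Immune activation genes were mostly higher in the tumour. In the interferon response list 30 of 31 tested members rose and 1 fell (31 adjusted over the list alone, adjusted p = 1.63e-11). The interferon-induced T cell attractants Cxcl10 and Cxcl9 rose from 2.82 ± 0.302 to 73.5 ± 1.60 FPKM and from 3.66 ± 0.191 to 55.9 ± 2.17. All 17 members of the MHC class I list rose (17 adjusted over the list alone, adjusted p = 6.17e-08, and 0.0506 as adjusted p with an estimated correlation), among them the peptide transporter Tap1 (48.6 ± 1.35 and 165 ± 4.38 FPKM) and the proteasome activator Psme2 (82.3 ± 5.30 and 267 ± 8.80). In the inflammatory activation list 13 of 17 members rose and 3 fell (16 adjusted over the list alone, adjusted p = 0.000521). Nos2, the inducible nitric oxide synthase, rose from 0.133 ± 0.0607 to 30.8 ± 0.859 FPKM, and Acod1, which makes itaconate, from 6.27 ± 0.368 to 100 ± 3.46. Chemokines moved both ways, with 14 of 24 risen and 7 fallen (22 adjusted over the list alone). Their list was called higher (adjusted p = 0.0450) but not with an estimated correlation (adjusted p = 0.396), nor without cKO-labelled TAM replicate 1, which enters the fit through its variance. The call was also lost when rescaled (adjusted p = 0.113), quantile normalized (0.0517) or fitted with these 2 groups only. Pf4 fell from 1320 ± 47.3 to 216 ± 10.4 FPKM. Of the NF-kB feedback genes 11 of 18 rose and 5 fell (17 adjusted over the list alone, adjusted p = 0.0455, and 0.143 as adjusted p with an estimated correlation), a call lost without resident replicate 3 or control TAM replicate 2, with the replicate block and with no variance trend. Ier3 stood at 43.5 ± 2.28 and 179 ± 4.06 FPKM. The dissociation, neutrophil and eosinophil lists were also higher in these libraries, as given below.

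The alternative activation, MHC class II, T cell ligand and tryptophan lists were not called. Of the alternative activation genes 11 of 20 rose and 6 fell (18 adjusted over the list alone, adjusted p = 0.174). Arg1 and Chil3 rose, while Retnla, a resistin-like secreted protein, fell from 10265 ± 482 to 241 ± 8.39 FPKM and the lectin Mgl2 from 795 ± 3.12 to 36.0 ± 1.76. Of the MHC class II list 3 of 12 rose and 8 fell (11 adjusted over the list alone, adjusted p = 0.0943), and 6 rose and 6 fell under quantile normalization. H2-Eb1 fell from 5937 ± 162 to 3517 ± 84.2 FPKM and the invariant chain Cd74 from 25967 ± 762 to 16820 ± 230, whereas the protease Ctss, which trims the invariant chain, rose from 1968 ± 34.9 to 3801 ± 108. Cd74 moved the other way under quantile normalization, where its log2 change was 0.12. Ligands that regulate T cells rose in 11 of 18 cases and fell in 6 (17 adjusted over the list alone, adjusted p = 0.0795). Cd274, which encodes PD-L1, rose from 3.69 ± 0.253 to 68.0 ± 0.374 FPKM. In the tryptophan metabolism list 9 of 13 rose and 4 fell (13 adjusted over the list alone, adjusted p = 0.289). The first enzymes of the kynurenine pathway, Ido1 and Tdo2, rose from 0.211 ± 0.232 to 22.2 ± 0.455 FPKM and from 0.168 ± 0.00537 to 2.98 ± 0.282, and the monoamine oxidase Maoa fell from 14.4 ± 0.909 to 2.16 ± 0.128.

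Hypoxia and glycolysis genes were higher in control TAM than in resident macrophages. All 20 tested hypoxia genes rose (20 adjusted over the list alone, median log2 change 2.10, adjusted p = 4.74e-10), led by the oxygen-sensing hydroxylase Egln3 (0.383 ± 0.157 and 61.4 ± 0.540 FPKM) and the angiogenic factor Vegfa (0.854 ± 0.0874 and 48.7 ± 0.813). In the glycolysis list 18 of 21 rose and 2 fell (20 adjusted over the list alone, adjusted p = 1.61e-08), and the glucose transporter Slc2a1 went from 3.52 ± 0.442 to 94.4 ± 1.28 FPKM. Of the oxidative phosphorylation genes 31 of 33 rose and 2 fell, by smaller steps (33 adjusted over the list alone, median log2 change 0.47, adjusted p = 2.19e-06, and 0.0856 as adjusted p with an estimated correlation). Cox7b rose from 53.4 ± 2.77 to 98.0 ± 3.61 FPKM. Of the cell cycle genes 27 of 28 rose (27 adjusted over the list alone, adjusted p = 1.61e-08), including the mitotic kinase gene Bub1 from 0.839 ± 0.0843 to 5.06 ± 0.109 FPKM. Matrix remodelling genes rose in 18 of 21 cases and fell in 2 (20 adjusted over the list alone, adjusted p = 4.41e-06). The membrane-bound metalloproteinase Mmp14 stood at 4.59 ± 0.654 and 65.1 ± 2.32 FPKM. The fibroblast and epithelial lists were also higher in the same libraries, as given below. The complement and scavenging list was called lower, with 6 of 22 risen and 15 fallen (21 adjusted over the list alone, adjusted p = 0.0165, and 0.0514 as adjusted p with an estimated correlation), but not under quantile normalization (adjusted p = 0.0629). The prostaglandin-degrading enzyme Hpgd fell from 186 ± 12.3 to 5.64 ± 0.359 FPKM. The lipid and lysosome list was not called, with 13 of 25 risen and 8 fallen (21 adjusted over the list alone, adjusted p = 0.159), but was called higher under quantile normalization (adjusted p = 0.0215). The tetraspanin Cd9 rose from 48.2 ± 0.912 to 505 ± 7.19 FPKM and the fatty acid receptor Cd36 fell from 376 ± 23.5 to 32.0 ± 1.28. The early genes that tissue dissociation induces were called higher, with 14 of 18 risen and 3 fallen (17 adjusted over the list alone, adjusted p = 0.00417, and 0.129 as adjusted p with an estimated correlation). Junb stood at 371 ± 19.7 and 784 ± 14.2 FPKM.

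Genes listed as markers of other cell types differed between the sorts. Acinar enzyme genes summed to 34703 ± 980 FPKM in resident libraries (6.49% of all FPKM) and 119 ± 3.30 in control TAM, and all 24 tested members fell (24 adjusted over the list alone, adjusted p = 5.38e-20). The 5 largest falls of named genes were all acinar products, Pnlip, Cel, Cela2a, Clps and Ctrl, with Cela2a going from 6034 ± 298 to 10.8 ± 0.543 FPKM. All 8 B and plasma cell genes fell (8 adjusted over the list alone, adjusted p = 1.73e-05), Ighm from 854 ± 7.55 to 83.1 ± 4.18 FPKM. Dendritic cell genes fell in 6 of 10 cases and rose in 2 (8 adjusted over the list alone, adjusted p = 0.0165, and 0.0591 as adjusted p with an estimated correlation), with Cst3, which macrophages also express, at 3361 ± 133 and 1236 ± 16.7 FPKM. Markers of other types were higher in control TAM. Neutrophil genes rose in 11 of 12 cases and fell in 0 (11 adjusted over the list alone, adjusted p = 4.41e-06), and S100a9 stood at 0.0320 ± 0.0641 and 25.4 ± 3.21 FPKM. Eosinophil genes rose in 5 of 6 cases and fell in 1 (6 adjusted over the list alone, adjusted p = 0.00402). Siglecf stood at 0.494 ± 0.164 and 15.3 ± 1.03 FPKM, Alox15 at 137 ± 3.64 and 1389 ± 20.9, and Prg2 listed at 0 in every resident library and at 34.4 ± 0.792 FPKM in control TAM. Epithelial genes rose in 13 of 14 cases and fell in 1 (14 adjusted over the list alone, adjusted p = 7.34e-06). The keratin Krt19 stood at 1.76 ± 0.401 and 82.2 ± 3.75 FPKM. Fibroblast genes rose in 9 of 11 cases and fell in 0 (9 adjusted over the list alone, adjusted p = 0.000521). The collagen Col3a1 stood at 6.75 ± 0.352 and 61.2 ± 1.39 FPKM. T and NK cell genes rose in 11 of 13 cases and fell in 1 (12 adjusted over the list alone, adjusted p = 0.0112, and 0.168 as adjusted p with an estimated correlation). Il7r stood at 0.242 ± 0.0892 and 2.87 ± 0.392 FPKM. Islet genes rose in 4 of 5 cases and fell in 1 (5 adjusted over the list alone, adjusted p = 0.0340, and 0.0885 as adjusted p with an estimated correlation), a call also lost when rescaled and at a pseudocount of 0.1. The insulin gene Ins2 stood at 2.38 ± 0.629 and 64.7 ± 6.15 FPKM. Endothelial genes were not called, with 4 of 6 risen and 0 fallen (4 adjusted over the list alone, adjusted p = 0.0714). The macrophage identity list was not called either, with 6 of 13 risen and 6 fallen (12 adjusted over the list alone, adjusted p = 0.788). Its median change was above 0 and its test pointed lower, or higher when rescaled or quantile normalized. Csf1r, the receptor that sustains macrophages, fell from 1238 ± 6.40 to 534 ± 7.65 FPKM, and Itgam, which encodes CD11b, rose from 31.4 ± 0.995 to 75.9 ± 5.23. No member of the mast cell and erythroid lists passed the filter on low values.

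In all, 8577 of 11127 genes tested differed between control TAM and resident macrophages at an adjusted p under 0.05 (limma on log2(FPKM + 1)), 4337 higher and 4240 lower, and 1883 of them by at least 2-fold, 1110 higher and 773 lower (2566 at a pseudocount of 0.1, 2327 when rescaled and 2663 by voom). The values of the groups did not overlap for 8218 genes (73.9%, where chance gives 5.71%). Camera called 23 of 32 lists, of which 14 were also called with an estimated correlation. Rescaling each library to a common total moved the median change of all genes up by 0.19 on the log2 scale, and 66.0% of the calls were then higher against 50.6%. The genotype label also differs between these groups (wild type and Ahr fl/fl), and so did Y-linked transcripts, with Ddx3y at 0.0265 ± 0.0258 FPKM in resident and 0.656 ± 0.122 in control TAM libraries. The labels do not say which of the 2 extraction kits each library had.

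**Figure D2:**
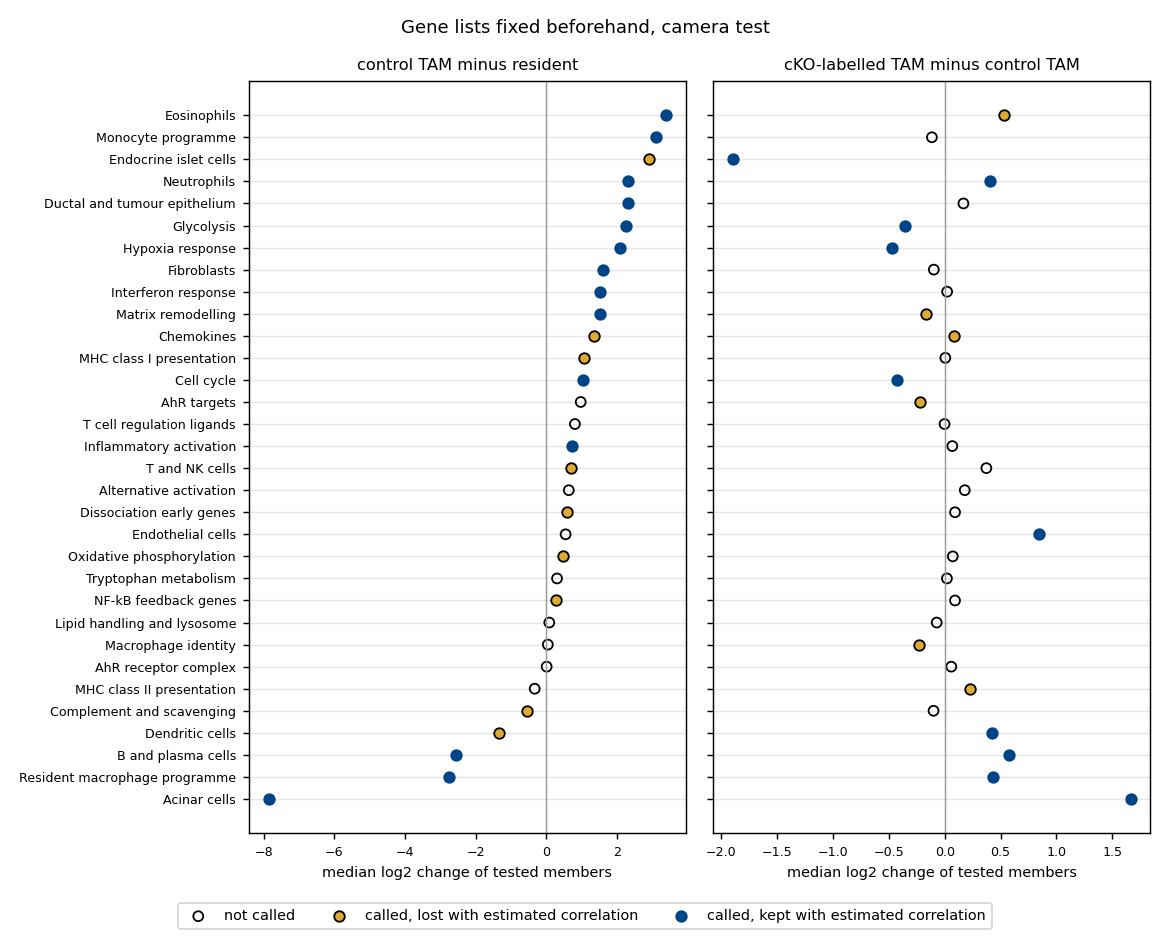
Median log2 change of the tested members of each of the 32 gene lists, control TAM minus resident macrophages (left) and cKO-labelled minus control TAM (right), on different x scales. Filled points are lists called by camera (blue where kept and yellow where lost with an estimated correlation), and the resident programme lies at -2.76 on the left and 0.44 on the right, and the hypoxia list at 2.10 and -0.47.

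The second comparison asked what changes in tumour macrophages when Ahr is targeted in Lyz2-expressing cells. Among the largest rises, Cd209f rose from 1.54 ± 0.140 FPKM in control TAM to 61.3 ± 2.46 in cKO-labelled TAM, the cysteine protease Ctsk, at 0.636 ± 0.0594 in resident macrophages, from 8.23 ± 1.52 to 96.0 ± 1.71, and the chemokine Ccl8 from 191 ± 3.45 to 1548 ± 93.7. Plvap, a protein of endothelial diaphragms, rose from 0.863 ± 0.402 to 16.6 ± 1.12 FPKM, and Clps, the pancreatic colipase, from 4.42 ± 0.962 to 43.8 ± 2.88. The largest falls were those of the insulin genes Ins2 (64.7 ± 6.15 and 2.81 ± 0.971 FPKM) and Ins1 (16.0 ± 1.59 and 0.375 ± 0.186). Prl2c3, Spink2 and Ucp1 followed, at 20.8 ± 2.03 and 4.77 ± 0.353, 17.2 ± 1.69 and 3.88 ± 0.546, and 34.3 ± 1.06 and 9.36 ± 0.580 FPKM. Reads of the Prl2c, Ins, Cd209 and Clec10a-Mgl2 families can be split between near-identical copies, so single members of these are uncertain.

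Of the resident macrophage programme 15 of 21 tested members rose and 5 fell (20 adjusted over the list alone, median log2 change 0.44, adjusted p = 2.61e-08). Cbr2, a carbonyl reductase, rose from 62.8 ± 1.51 to 279 ± 8.46 FPKM, Gas6 from 21.8 ± 0.314 to 82.5 ± 0.972 and Cd209g from 0.541 ± 0.0823 to 9.89 ± 0.329. Among the 5 that fell, Timd4 went from 91.2 ± 3.82 to 68.8 ± 0.796 FPKM and Vsig4 from 95.4 ± 3.47 to 72.5 ± 3.03. Their levels in resident macrophages were higher, at 213 ± 3.43 and 129 ± 7.05. In the alternative activation list 10 of 20 rose and 6 fell (16 adjusted over the list alone), and the list was not called (adjusted p = 0.0547), but was without control TAM replicate 1 or 2 or cKO-labelled replicate 1 or 3, and when rescaled or quantile normalized. Retnla rose from 241 ± 8.39 to 1306 ± 86.1 FPKM, Clec10a from 26.4 ± 1.81 to 120 ± 3.02 and Mgl2 from 36.0 ± 1.76 to 154 ± 2.94. In contrast, the abundant Arg1 fell from 3269 ± 55.3 to 1968 ± 56.0 FPKM (adjusted p = 6.55e-10) and Chil3 from 399 ± 3.71 to 266 ± 3.56 (adjusted p = 1.72e-06). The summed FPKM of the list fell from 6297 to 5440. The MHC class II list was called higher, with 7 of 12 risen and 4 fallen (11 adjusted over the list alone, adjusted p = 0.0195), a call lost with an estimated correlation (adjusted p = 0.282), under quantile normalization (adjusted p = 0.0690) and with no variance trend. H2-Eb1 rose from 3517 ± 84.2 to 5174 ± 51.4 FPKM, H2-Aa from 5131 ± 91.2 to 7040 ± 111 and Cd74 from 16820 ± 230 to 23527 ± 411. Chemokines were called higher, with 10 of 24 risen and 4 fallen (15 adjusted over the list alone, adjusted p = 0.0117, and 0.398 as adjusted p with an estimated correlation), and Pf4 stood at 216 ± 10.4 and 371 ± 29.2 FPKM. In the same libraries the acinar, B cell, dendritic cell and endothelial lists were also higher, as given below.

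Hypoxia, glycolysis and cell cycle genes were lower in cKO-labelled TAM, by less than 2-fold in the median. Of the hypoxia genes 17 of 20 fell and 0 rose (17 adjusted over the list alone, median log2 change -0.47, adjusted p = 4.21e-11). The vasodilator peptide gene Adm fell from 28.4 ± 1.88 to 10.2 ± 0.629 FPKM and Egln3 from 61.4 ± 0.540 to 28.7 ± 0.543. Of the glycolysis genes 19 of 21 fell and 1 rose (20 adjusted over the list alone, median log2 change -0.35, adjusted p = 3.95e-10), among them lactate dehydrogenase Ldha (1574 ± 7.72 and 1158 ± 28.9 FPKM) and aldolase Aldoa (1714 ± 23.7 and 1224 ± 20.3). Of the cell cycle genes 25 of 28 fell and 0 rose (28 adjusted over the list alone, median log2 change -0.43, adjusted p = 5.34e-12). The mitotic cyclin Ccnb2 stood at 26.8 ± 1.52 and 15.9 ± 0.910 FPKM and Bub1 at 5.06 ± 0.109 and 2.72 ± 0.433. Matrix remodelling genes were called lower, with 2 of 21 risen and 11 fallen (13 adjusted over the list alone, adjusted p = 0.0118, and 0.0520 as adjusted p with an estimated correlation). Mmp19 fell from 9.02 ± 0.818 to 5.30 ± 0.128 FPKM, while the gelatinase Mmp9 rose from 41.5 ± 0.324 to 123 ± 4.28. In the same libraries the macrophage identity and islet lists were also lower, and the acinar, B cell and neutrophil lists higher, as given below. Of 15 markers of large peritoneal macrophages, a list written after the results were seen, 7 fell and 2 rose.

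The inflammatory, interferon and tryptophan lists were not called. In the inflammatory activation list 7 of 17 rose and 4 fell (11 adjusted over the list alone, adjusted p = 0.546). Nos2 fell from 30.8 ± 0.859 to 11.4 ± 1.28 FPKM and Acod1 from 100 ± 3.46 to 75.2 ± 1.62, and Il1b rose from 254 ± 6.11 to 314 ± 5.33. In the interferon response list 6 of 31 rose and 9 fell (16 adjusted over the list alone, adjusted p = 0.361), with Ifit2 falling from 32.2 ± 1.13 to 19.1 ± 1.58 FPKM and Gbp3 from 184 ± 2.95 to 138 ± 3.24. In the tryptophan metabolism list 3 of 13 rose and 4 fell (7 adjusted over the list alone, adjusted p = 0.376). Tdo2 fell from 2.98 ± 0.282 to 0.665 ± 0.0818 FPKM, Ido1 from 22.2 ± 0.455 to 13.4 ± 0.781, and Wars, the tryptophanyl-tRNA synthetase, from 108 ± 1.84 to 68.8 ± 0.361. In the T cell ligand list 6 of 18 rose and 7 fell (14 adjusted over the list alone, adjusted p = 0.691), and Pdcd1lg2, which encodes PD-L2, rose from 5.50 ± 0.429 to 8.56 ± 1.11 FPKM. The calls of Ido1 and Pdcd1lg2 were lost at a pseudocount of 0.1, where their log2 changes were no smaller (-0.73 and 0.62, against -0.69 and 0.55). In the lipid and lysosome list 6 of 25 rose and 10 fell (17 adjusted over the list alone, adjusted p = 0.178), with apolipoprotein Apoe rising from 6454 ± 206 to 14264 ± 455 FPKM and Gpnmb falling from 35.4 ± 1.07 to 12.3 ± 0.961. In the complement and scavenging list 8 of 22 rose and 11 fell (19 adjusted over the list alone, adjusted p = 0.362), and Hpgd stood at 5.64 ± 0.359 and 14.9 ± 0.785 FPKM. MHC class I genes rose in 1 of 17 cases and fell in 6 (7 adjusted over the list alone, adjusted p = 0.315). Their list was called lower when rescaled (adjusted p = 0.0411) and under quantile normalization (0.0113), and Tapbp fell from 405 ± 3.23 to 347 ± 6.99 FPKM. The monocyte programme had 3 of 15 risen and 5 fallen (9 adjusted over the list alone, adjusted p = 0.448). Ly6c2 stood at 24.1 ± 1.11 and 18.6 ± 1.68 FPKM. NF-kB feedback genes had 8 of 18 risen and 3 fallen (13 adjusted over the list alone, adjusted p = 0.309). Nfkb2 stood at 36.5 ± 0.958 and 47.0 ± 1.76 FPKM and Tnfaip3 at 20.5 ± 0.489 and 14.9 ± 1.04. Oxidative phosphorylation genes had 11 of 33 risen and 2 fallen (14 adjusted over the list alone, adjusted p = 0.143), and were called higher without cKO-labelled replicate 1. Ndufa4 stood at 47.2 ± 3.91 and 86.5 ± 8.05 FPKM. The dissociation genes had 7 of 18 risen and 3 fallen (10 adjusted over the list alone, adjusted p = 0.186). Hspa8 stood at 123 ± 4.15 and 161 ± 4.87. For the inflammatory, interferon, MHC class I and tryptophan lists, the median change was above 0 and the mean below it. The test pointed lower in the last 3 and higher in the first. The medians of all 4 fell below 0 when rescaled, as did that of the oxidative phosphorylation list. Counts of members also turned with rescaling. Of the NF-kB feedback genes 5 then rose and 6 fell, and of the dissociation genes likewise 5 and 6. For oxidative phosphorylation these were 2 and 6, and for inflammatory activation 2 and 4.

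Markers of most other cell types were higher in the cKO-labelled libraries, with the islet list as the exception among the lists called. Acinar genes rose in 21 of 24 cases and fell in 1 (22 adjusted over the list alone, median log2 change 1.66, adjusted p = 1.65e-25), Prss2 from 22.1 ± 1.26 to 79.0 ± 1.45 FPKM, and their sum was 437 ± 8.06 FPKM against 119 ± 3.30. B and plasma cell genes rose in 6 of 8 cases and fell in 0 (6 adjusted over the list alone, adjusted p = 6.17e-05), Ighm from 83.1 ± 4.18 to 220 ± 2.16 FPKM. Endothelial genes rose in 5 of 6 cases and fell in 1 (6 adjusted over the list alone, adjusted p = 0.00261). Dendritic cell genes rose in 7 of 10 cases and fell in 0 (7 adjusted over the list alone, adjusted p = 0.000289). Cd209a stood at 17.7 ± 0.739 and 43.7 ± 0.788 FPKM. Neutrophil genes rose in 9 of 12 cases and fell in 1 (10 adjusted over the list alone, adjusted p = 0.000788), S100a9 from 25.4 ± 3.21 to 57.0 ± 3.44 FPKM. Eosinophil genes rose in 4 of 6 cases and fell in 0 (4 adjusted over the list alone, adjusted p = 0.0128, and 0.0638 as adjusted p with an estimated correlation), a call also lost at a pseudocount of 0.1. Siglecf rose from 15.3 ± 1.03 to 27.0 ± 0.659 FPKM. Islet genes fell in 4 of 5 cases and rose in 1 (5 adjusted over the list alone, median log2 change -1.89, adjusted p = 0.000996). The epithelial list was not called (5 of 14 risen, 2 fallen, 7 adjusted over the list alone, adjusted p = 0.143). Its member Krt18 stood at 93.2 ± 1.34 and 107 ± 4.84 FPKM (adjusted p = 0.0827). Krt18 passed the threshold without resident replicate 1 or 3, with these 2 groups only (limma adjusted p = 0.00155) and by voom (adjusted p = 0.00291). Nor was the fibroblast list called (3 of 11 risen, 4 fallen, 9 adjusted over the list alone, adjusted p = 0.630), in which Dcn fell from 52.9 ± 0.366 to 24.4 ± 0.947 FPKM, nor the T and NK cell list (7 of 13 risen, 1 fallen, 9 adjusted over the list alone, adjusted p = 0.0701). The latter was called higher when rescaled (adjusted p = 0.0210), quantile normalized (0.0437) or without control TAM replicate 1. Its member Klrk1 rose from 5.59 ± 0.327 to 8.37 ± 0.138 FPKM. The macrophage identity list was called lower, with 2 of 13 risen and 8 fallen (10 adjusted over the list alone, adjusted p = 0.0117, and 0.0520 as adjusted p with an estimated correlation). Lyz2 is among those that fell, and the adaptor Tyrobp rose from 2040 ± 81.0 to 2535 ± 95.1.

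**Figure D3:**
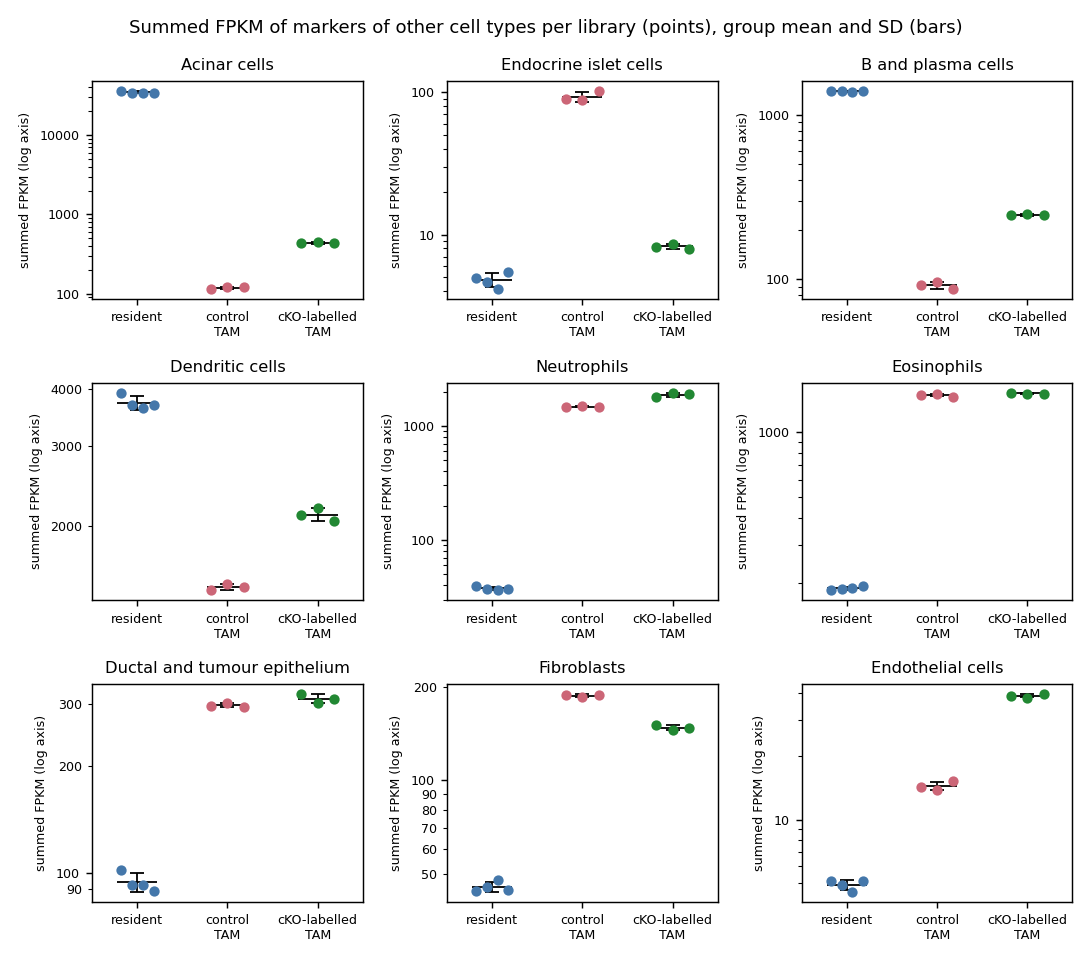
Summed FPKM (log axes) of the markers of 9 other cell types in each library (points), with group means and SD (bars). Acinar RNA averages 34703 FPKM in resident, 119 in control TAM and 437 in cKO-labelled TAM libraries, and islet RNA 4.80, 93.4 and 8.26. In control TAM, Alox15 (1389 FPKM) makes up most of the eosinophil sum (1480) and Retnlg (1166) most of the neutrophil sum (1473).

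In all, 4410 of 11127 genes tested differed between cKO-labelled and control TAM at an adjusted p under 0.05, 2283 higher and 2127 lower, and 147 of them by at least 2-fold, 112 higher and 35 lower. The 2-fold count depends on the scale, with 280 at a pseudocount of 0.1, 193 when rescaled and 311 by voom. The values of the groups did not overlap for 5715 genes (51.4%, where chance gives 10%). Camera called 16 of 32 lists, and 10 of these calls were kept with an estimated correlation. With each library rescaled to a common total, 32.8% of the calls were higher, against 51.8% as deposited.

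The changes of the comparisons ran against each other across genes. Of the 112 genes at least 2-fold higher in cKO-labelled than in control TAM, 69 were at least 2-fold lower in control TAM than in resident macrophages, where independent lists would share 7.78 (a number that leaves the shared control libraries out of account). Conversely, 28 of the 35 genes at least 2-fold lower were at least 2-fold higher in control TAM, where independent lists would share 3.49. Without the 2-fold limit, 1231 genes were lower in control TAM and higher in cKO-labelled TAM (869.9 for independent lists), and 1265 were higher and then lower (829.05). Other genes moved the same way in both comparisons, 532 lower and 628 higher (810.5 and 889.9 for independent lists). With the 2-fold limit these were 1 and 16 (2.43 and 11.2 for independent lists). The covariance of the log2 changes was -0.128. Since control TAM enter both comparisons, groups without any effect were simulated against them, which gave a mean covariance of -0.00381, so the difference was -0.124. The correlation across genes, which are not independent replicates, was -0.40, and -0.53 in the simulated groups. To remove the sharing, the control TAM libraries were also divided, 1 for one comparison and 2 for the other, in all 6 ways (chosen after seeing the data). The correlation was then -0.39 to -0.37 and the covariance -0.125 to -0.123. Of the 107 to 120 genes at least 2-fold higher in cKO-labelled TAM, 65 to 73 were at least 2-fold lower in control TAM (7.68 to 8.44 for independent lists). Of the 32 to 38 at least 2-fold lower, 25 to 31 were at least 2-fold higher there (3.22 to 3.78).

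**Figure D4:**
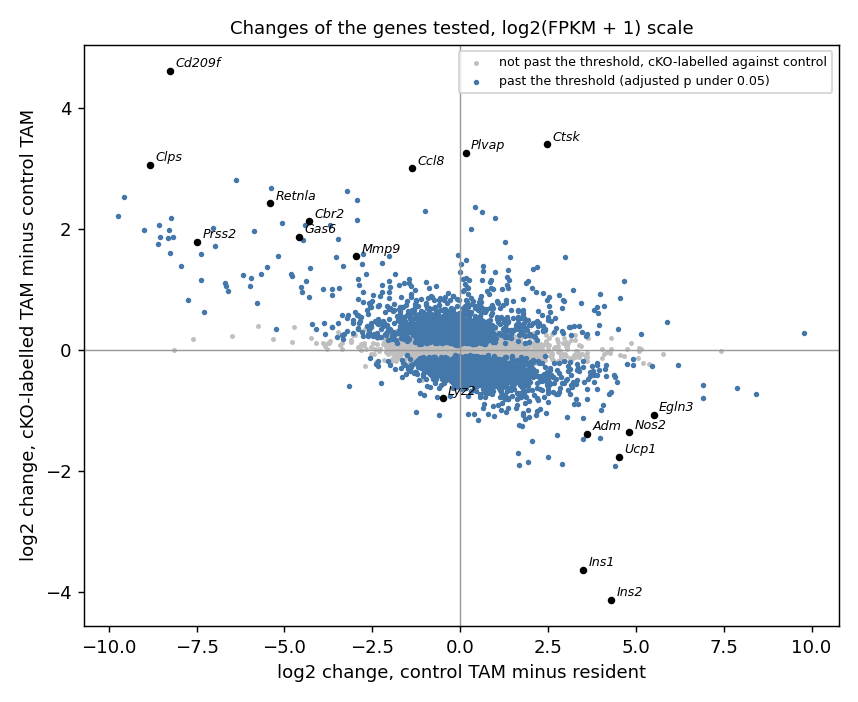
Log2 change of each of the 11127 genes tested, control TAM minus resident macrophages on the x axis and cKO-labelled minus control TAM on the y axis, on the log2(FPKM + 1) scale, with genes past the threshold in the second comparison in blue and labelled genes in black. Cd209f and Retnla lie at upper left, and Egln3, Nos2, Ins1 and Ins2 at lower right.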

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

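The tests of this part were chosen after the results were seen, except the count of other splits of the samples, which was planned but whose reading was also written afterwards.

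In 9 of 104 checks of single measures over the 4 resident libraries, 1 library stood apart from the other 3 by most of their range; chance gives about 1 in 20. For S100a9 and Prl2c3 the other 3 values were 0, so these flags follow from near-zero detection and do not bear on that comparison. The libraries that stood apart were the highest for Cel (2606 FPKM), Cd74 (27108), Il7r (0.374), Mmp19 (2.23), Tapbp (251), S100a9 (0.128) and Prl2c3 (0.0783), and the lowest for Cox7b (49.3) and Ctsk (0.547).

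For control TAM against resident macrophages, 1 of the 35 splits of these 7 libraries into groups of 3 and 4 gave as many genes as the real one (8577), which is the real split itself. The highest of the others gave 4542, so no other grouping of these libraries gave as many. Libraries of a group may come from 1 pool, which would favour the real split, so the count says nothing about the spread between mice. For cKO-labelled against control TAM there are 10 splits, too few for a share under 0.05. The real split (the 1 with that many genes) gave 4410 in limma and the highest other gave 0, with 200 to 532 genes at an unadjusted p under 0.05 in the others.

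The cKO-labelled libraries lay toward the resident profile, beyond what library noise in shared controls gives, as the covariance of the changes was -0.128, the lowest simulated one -0.00409, and that with separate controls -0.125 to -0.123, which a difference common to all control libraries would also give. An even admixture of resident material would give every gene at least 8-fold lower in control TAM the same implied share, (cKO - control) / (resident - control). The 21 acinar genes gave a median of 0.910% (highest 5.04%), but of the 9 such resident macrophage genes 66.7% lay above that highest one and 55.6% outside a factor of 2 from their own median of 7.35% (0.328% for Cd163, 18.2% for Cbr2), as did 45% and 65% in a first set of 40 genes (median 3.21%), replaced after it was seen to hold acinar and immunoglobulin genes. A lower share of macrophages in the sort, with the mix of other cells unchanged, would raise all other cell types alike. The islet list moved by -1.89 (median log2 change) and the acinar list by 1.66, which argues only against that form. The mix of other cells may differ between tumours. The macrophage identity list was lower (8 of 13 fell), and the acinar, B cell, endothelial, dendritic, neutrophil and eosinophil lists were higher, as a lower share would give. Camera with an estimated correlation lost the identity and eosinophil calls (adjusted p = 0.0520 and 0.0638). Other macrophage genes rose, which a lower share alone would not give. These were 2 of the 13, Tyrobp among them, and 15 of 21 of the resident programme, of which 5 fell. Still open as hypotheses are a changed mix of macrophage subsets and a lower share of macrophages with a changed mix of other cells. A small carry-over of acinar RNA beside them also stays open, free or with cells, as the purity of the sort was not measured. So does an untested effect of the genotype.

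Libraries of a group differed little. The same library deposited more than once is argued against by the lowest pair, whose squared differences had a median of 1.76 times counting noise. Genes of other cell types, whose carry-over could differ between dissections, varied like other genes of the same level, with median ratios of their coefficients of variation of 1.07 in resident, 1.16 in control TAM and 0.718 in cKO-labelled libraries. This is consistent with libraries made from 1 pool per group, for which the p-values would not cover the spread between mice. Mice handled alike may give the same picture, which these data do not separate from a pool.

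Ahr was higher and Lyz2 lower in the cKO-labelled libraries. An exchange of the genotype labels of the tumour groups would put the lower Lyz2, the locus with the Cre insertion, in the control libraries. Lyz2 instead moved by -0.80 (log2) in the cKO-labelled ones. However, Lyz2 is also in the macrophage identity list, of which 8 of 13 members fell in these libraries. It also differed between resident and control TAM libraries (28140 and 19904 FPKM), of which neither is labelled as carrying LysM. A changed cell mix could thus lower Lyz2 too, so its fall does not settle the labels. In the cKO-labelled libraries 4 AhR targets fell and 0 rose, while 2127 of all 11127 genes tested fell. Of 15 peritoneal macrophage markers, 7 fell and 2 rose there (median log2 change -0.09). A changed cell mix could also lower the targets, so their count does not decide. Assignment of Lyz2 reads to its near copy Lyz1, which went from 146 ± 1.56 to 819 ± 20.4 FPKM, does not suffice, since the sum of both changed by -0.71. A biological explanation, the loss of 1 Lyz2 copy to the insertion, is open and was not tested, as were reads of the Ahr exons that Cre leaves in place.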

How the results depend on the processing

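Under the alternatives that keep all libraries and the filter, 8396 (replicate block) to 8738 (rescaled) genes differed between control TAM and resident macrophages, and 4201 (pseudocount 0.1) to 4771 (voom) between cKO-labelled and control TAM, with 4342 under the replicate block. Requiring an FPKM of 5, which left 7582 genes, gave 6158 and 3629, and no filter gave 9416 and 4595. The 2-fold limit left 1883 and 147 genes, but 2566 and 280 at a pseudocount of 0.1, 2220 and 195 at 0.5, 2663 and 311 by voom, 2327 and 193 when rescaled, and 1390 and 115 at an FPKM of 5; without 1 library it left 1881 to 1902 and 141 to 150. Leaving out 1 library gave 8237 to 8559 and 3496 to 4611 genes. Camera with an estimated correlation called 14 and 10 lists against 23 and 16. Fry, which does not compare a list with other genes, called 31 and 27 of 32. Without 1 library camera called 22 or 23 and 16 to 18. The log2 change of Ahr between cKO-labelled and control TAM kept its direction and its side of the threshold under every alternative (0.40 to 0.52, and 0.42 to 0.52 without 1 library).

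Cd74 and Lyz2, lower in control TAM than in resident libraries, were reversed under quantile normalization (log2 changes of 0.12 and 0.073). That scaling gives the highest gene of every library the same value. Lyz2 was the highest gene in every control TAM library and in resident replicates 2, 3 and 4. Its fall could therefore not show under that scaling. For Cd74 the cause was not tested. Lpcat2 in the second comparison (log2 change -0.0069, not past the threshold) was reversed without control TAM replicate 1 (0.0058) or cKO-labelled replicate 2 (0.021), and lay at -0.030 to 0.021 without 1 library. Of the other values of named genes under alternatives, 3008 kept direction and side, 3 lost the threshold (Ido1 and Pdcd1lg2 in the second comparison at a pseudocount of 0.1, Cd93 in the first when rescaled) and 4, all of Krt18, passed it. Voom on recovered reads (chosen after seeing the data) called 8564 and 4771 genes, with 60.2% and 44.6% higher; without the acinar genes and rescaled (also chosen after) these were 59.4% and 32.7% higher, and the median change of the first comparison moved to 0.10.

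Calls of single lists also depended on the processing. In the first comparison, chemokines were lost when rescaled, quantile normalized, fitted with 2 groups only, by voom, without the acinar genes, or without cKO-labelled replicate 1. NF-kB feedback genes were lost with the replicate block, with no variance trend, or without resident replicate 3 or control TAM replicate 2. At an FPKM of 5 both were lost. Islet genes were lost at a pseudocount of 0.1, when rescaled, by voom and without the acinar genes, T and NK cell genes by voom, and complement under quantile normalization, which added the lipid list. In the second comparison, MHC class II was lost under quantile normalization and with no variance trend, eosinophils at a pseudocount of 0.1, AhR targets with no filter, and chemokines and matrix remodelling at an FPKM of 5. MHC class I, T and NK cells and alternative activation were gained when rescaled, quantile normalized or without the acinar genes. Alternative activation was also gained with no filter and without any of 4 single libraries, T and NK cells without control TAM replicate 1, and oxidative phosphorylation without cKO-labelled replicate 1. At an FPKM of 5 only 28 lists kept enough members to be tested, and the AhR target, endothelial, islet, and T and NK cell lists did not. The causes were not tested.

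Replicate numbers did not pair the libraries: deviations of same-numbered cKO-labelled and control TAM libraries correlated at -0.0442 to 0.0884, and those of other numbers at -0.133 to 0.122. Depth limits genes of few FPKM, where the spread was widest (median coefficient of variation 8.95% to 11.0% at 1 to 5 FPKM).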

Other observations

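The tests of this part were chosen after the results were seen.

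Alox15 and Serpinb2, which the macrophages of the peritoneal cavity express strongly, rose by 3.33 and 5.47 on the log2 scale in control TAM against resident macrophages. A candidate explanation is that large peritoneal macrophages, which carry CD11b and F4/80 and would not be removed by the sort, are part of the tumour libraries. Of 15 other markers of that cell type, 13 rose and 2 fell, with a median log2 change of 2.07 (camera p = 1.17e-05, and 0.00226 as p with an estimated correlation). That list left out Fn1, Thbs1, Fcna, Vsig4 and Timd4, whose values had been seen and of which Fcna, Vsig4 and Timd4 fell. With them, 15 of 20 rose and 5 fell, with a median of 1.25 (camera p = 0.000516, and 0.00682 as p with an estimated correlation). As these markers were chosen with part of the values known, the hypothesis stays open. Gata6, the transcription factor that defines these cells, went from 1.32 ± 0.148 FPKM in resident to 15.6 ± 0.549 in control TAM and 9.78 ± 0.626 in cKO-labelled TAM. Saa3, the most abundant of the 15 in the tumour libraries, lay at 203 to 220 FPKM in resident libraries, 2166 to 2203 in control TAM and 2035 to 2153 in cKO-labelled TAM. Selp went from 14.0 ± 0.658 to 91.4 ± 4.24 and 85.8 ± 0.788. Cxcl13, also in the chemokine list, fell from 376 ± 16.0 to 70.5 ± 1.75 FPKM and Cd93 from 7.99 ± 0.236 to 6.32 ± 0.492. In cKO-labelled against control TAM, 2 of the 15 rose and 7 fell (median log2 change -0.09, limma camera p = 0.0147, and 0.0352 as p with an estimated correlation).

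Y-linked transcripts were lower in every resident library than in every tumour library. Ddx3y was at 0.0265 ± 0.0258 FPKM in resident, 0.656 ± 0.122 in control TAM and 0.707 ± 0.148 in cKO-labelled TAM libraries, and Eif2s3y at 0.00534 ± 0.0107, 0.958 ± 0.126 and 1.00 ± 0.154. Xist, transcribed from the inactive X chromosome, stood at 1.38 ± 0.142, 1.21 ± 0.103 and 0.980 ± 0.122 FPKM in the same groups.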
